A study of Mus musculus with 8 samples.

How the data were processed

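RNA was measured by sequencing in 8 libraries of group 3 innate lymphoid cells (ILC3s). The cells were taken from the lamina propria of the small intestine and separated by flow cytometry, from mice without Rag1, which have no T or B cells of their own. The libraries form 4 groups of 2: NKp46+ and NKp46− ILC3s from mice with floxed Setd2 alleles and no cre (control), and the same subsets from mice that also carry Rorc-cre (Setd2-deleted). Per the labels, each library came from 500000 cells of mice aged 8 weeks, pooled from males and females, and the libraries of a group are biological duplicates. The groups were taken from the titles and genotypes in the labels.

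The deposited values are FPKM, fragment counts scaled by transcript length and by library size, computed by the authors for 53379 genes in 8 value columns, all of which were used. Per the labels' protocols, RNA extracted with Trizol was treated with DNase and selected with oligo(dT) beads, and libraries were sequenced as 150 bp paired reads on an Illumina instrument. The submitters' processing notes name STAR 2.5, RSEM 1.2 and the builds GRCm38.p5 and mm10, and do not say which step used which. The deposited FPKM columns share one distribution. At 11942 rank positions with FPKM of at least 1 in every library, values differed between libraries by at most 1.80% (median 0.0910%). The highest value over all columns was 16155.73. Such columns are what quantile normalisation gives; the labels do not mention that step. It fixes the top value, so a gene at the top rank cannot rise, and it removes any difference in the overall distribution between libraries. FPKM columns summed to between 774891 and 774937. Sequencing depth is therefore unknown, whole reads could not be recovered, and no counting interval or detection floor is given. A value of 0 is described as listed at 0. For genes that overlap, lie antisense to one another or have near-identical copies, the sources used here do not say how reads were divided.

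In the table, 26 gene symbols had been turned into dates and were restored from their Ensembl gene IDs, of which 53274 (99.8%) were found in GENCODE M21, the source of the coordinates on GRCm38. Genes with FPKM of at least 1 in at least 2 libraries were kept (13018 genes). Values were tested as log2(FPKM + 1) with limma 3.58.1 in R 4.3.3, with a mean of each group fitted to all 8 libraries in one model, so that the groups share one estimate of the spread (4 residual degrees of freedom and 3.83 prior degrees of freedom), and with empirical Bayes moderation that follows the mean. The p-values measure the spread between libraries. Log2 changes are on this scale, which understates the change of genes with low values. Changes were called at a Benjamini-Hochberg adjusted p under 0.05 over all genes kept. The comparisons were Setd2-deleted against control in each subset, the difference between those changes (an interaction term), and NKp46+ against NKp46− ILC3s in control and in Setd2-deleted mice.

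Before the data were examined, 31 gene lists and 11 lists of markers of other cell types (1080 distinct genes, 1077 of them found) were fixed, with the tests, the alternatives and the rule for the genes named. The 40 lists with at least 5 genes kept were tested with camera at a preset inter-gene correlation of 0.01, with Benjamini-Hochberg adjustment over the lists. Camera with a correlation estimated per list, and fry, were the alternatives. The lists were written from general knowledge of these cells and were not chosen on these libraries. Counts of changed members are given over all genes and also adjusted over the list alone.

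Named genes follow a fixed rule. Setd2 and a lineage panel (Rorc, Ncr1, Ccr6, Tbx21, Gata3, Il22, Il17a, Csf2 and Ifng) were given in every comparison. The 6 largest rises and 6 largest falls were named in each comparison with control, in the subset comparison of control mice and in the interaction. They needed an adjusted p under 0.05 and a mean FPKM of at least 5 in the higher group, and, outside the interaction, libraries that do not overlap between the groups. Predicted genes, pseudogenes and antigen receptor segments were passed over. Up to 3 changed members of each list, by smallest p, were named for the comparisons with control, beside members that another part of the rule named, and where fewer genes passed, all that met the conditions were named.

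The test was run on simulated data with 200 of the 13018 genes changed. The changed genes were drawn from those with a mean above 2 on the log2 scale. Noise was normal and independent between genes, with the moderated spread of the real fit. The shares below therefore do not cover genes with low values, correlated genes or differences between pools of mice. For the NKp46+ comparison it recovered 10.4% of genes changed by 0.5 on the log2 scale, 61.2% of those changed by 1 and 100% of those changed by 2, with 6.56% false calls. The same shares for the NKp46− comparison were 5.97%, 58.2% and 100%, with 9.92% false calls. Alternatives were other pseudocounts (0.1 and 0.5), filters, scalings and variance models, a 2-fold threshold, only the 4 libraries compared, the replicate number as a block, and each library left out in turn. A term for the mix of sexes and a restriction to protein-coding genes were added after the data were seen. Other tools were Python 3.11.15, pandas 2.3.3, numpy 2.4.6, matplotlib 3.10.9 and, in R, data.table (version 1.17.8).

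The design has no mice with Rorc-cre and unfloxed Setd2, so an effect of the cre allele and an effect of Setd2 loss were not separable in any comparison with control.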

Results

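Gene expression was measured by RNA sequencing in 8 libraries of intestinal ILC3s, lymphocytes without rearranged antigen receptors that depend on the transcription factor RORγt (encoded by Rorc) and make IL-22 and IL-17. The cells were sorted into NKp46+ and NKp46− subsets (NKp46, encoded by Ncr1, is an activating receptor of natural killer cells and of some ILC3s). Each subset came from control mice and from mice in which Rorc-cre was to delete floxed Setd2, which encodes the enzyme that trimethylates lysine 36 of histone H3. Each group had 2 libraries. Depth is not known, because the deposited FPKM had been brought to one distribution across libraries. Replicates correlated at 0.973 to 0.982 (log2 values, across genes). In a principal component analysis the first component (38.2% of the variance) parted the subsets and the second (21.2%) parted the genotypes. The third (12.2%) set replicate 1 of the NKp46− controls apart, with a score of 35.0 against −16.1 to 7.41 in the other libraries.

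Setd2 (ENSMUSG00000044791, chromosome 9, 110532597 to 110618633 on GRCm38) was measured at 13.82 and 17.11 FPKM in NKp46+ control libraries and at 17.07 and 17.69 in their Setd2-deleted counterparts. In NKp46− ILC3s the values were 17.51 and 13.33 in controls and 11.38 and 16.39 in Setd2-deleted libraries. The log2 change was 0.17 (SE 0.21, adjusted p = 0.738) in NKp46+ and −0.15 (SE 0.21, adjusted p = 0.759) in NKp46− cells. A value for the whole gene does not check the loss of a floxed part, so the genotypes are taken from the labels.

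**Figure D1:**
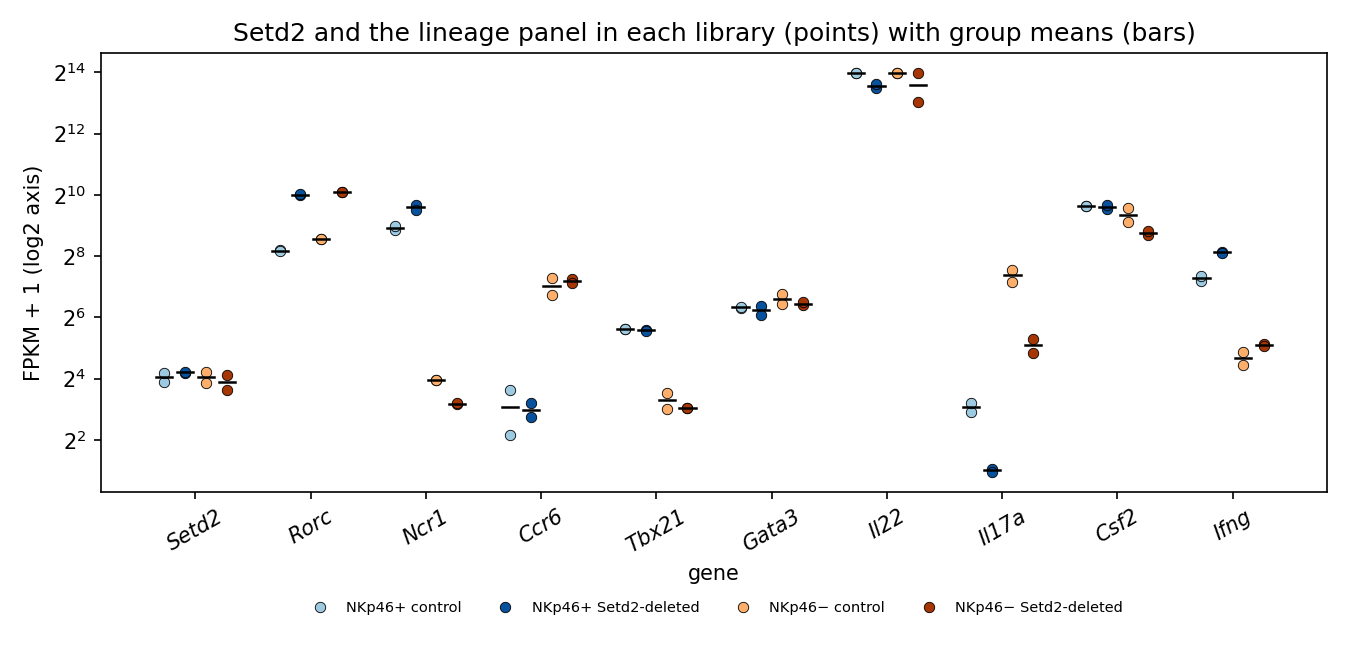
FPKM + 1 on a log2 axis for Setd2 and the lineage panel, with 1 point per library and a bar at the mean of each group of 2. Rorc lay at 283.90 to 375.24 FPKM in the 4 control libraries and at 1014.93 to 1100.55 in the 4 Setd2-deleted ones, while Setd2 overlapped between them.

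In NKp46+ ILC3s, the comparison of Setd2-deleted with control mice showed higher Rorc and higher genes of natural killer cells and type 1 responses, and lower Il17a. Rorc (ENSMUSG00000028150, chromosome 3, 94372794 to 94398276) went from 288 ± 6.12 to 1023 ± 12.0 FPKM (SD, n = 2), a log2 change of 1.82 (SE 0.08, adjusted p = 0.000313). Xcl1, a chemokine of natural killer and activated T cells, rose from 126 ± 5.04 to 543 ± 46.4 FPKM. Ifng, the type 1 cytokine, rose from 155 ± 12.9 to 279 ± 5.20 (log2 change 0.85, SE 0.14, adjusted p = 0.0352). Ncr1 rose from 486 ± 29.9 to 775 ± 59.1 (log2 change 0.67, SE 0.10, adjusted p = 0.0255). It is the gene of the sorting marker, so its level also depends on the sort. With 1 library left out the log2 changes were 0.76 to 0.93 for Ifng and 0.59 to 0.75 for Ncr1. Il17a (ENSMUSG00000025929, chromosome 1, 20730905 to 20734496) fell from 6.52 and 8.13 FPKM to 1.07 and 0.94 (log2 change −2.05, SE 0.20, adjusted p = 0.00675).

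Of 13018 genes tested, 249 changed in NKp46+ cells, 158 of them higher and 91 lower. The largest rises were in Gzma (granzyme A, log2 change 3.06, SE 0.48), Klrd1 (CD94, 2.72, SE 0.34), Klri2 (a killer-cell lectin-like receptor, 2.59, SE 0.18), Ociad2 (a membrane protein of endosomes, from 3.44 to 24.1 FPKM), Cpa3 (mast cell carboxypeptidase, 2.45, SE 0.31) and Tigit (an inhibitory receptor, 2.15, SE 0.18). Their adjusted p lay between 0.00199 (Klri2) and 0.0270 (Gzma). Gzma replicates were far apart, at 161.63 and 456.45 FPKM in Setd2-deleted cells against 23.85 and 41.92 in controls. The largest falls were in Pcp4 (a calmodulin-binding protein, −4.72, SE 0.32), Rpl29 (a ribosomal protein, −2.56, SE 0.31), Cdkn2c (an inhibitor of cyclin-dependent kinases, −2.28, SE 0.25), Blk (a Src-family kinase, −2.17, SE 0.16), Gria3 (a glutamate receptor subunit, −2.17, SE 0.21) and Hes1 (a Notch target, −2.11, SE 0.21). Pcp4 (ENSMUSG00000090223, chromosome 16, 96467606 to 96525793) went from 448 ± 17.3 to 17.1 ± 8.60 FPKM, and Rpl29 (ENSMUSG00000048758, chromosome 9, 106429454 to 106431568) from 60.6 ± 0.0141 to 9.44 ± 0.0707. An annotated transcript overlaps both Pcp4 and its neighbour Igsf5. The rest of the panel did not pass: Ccr6 (log2 change 0.08, adjusted p = 0.952), Tbx21 (−0.04, 0.927), Gata3 (−0.10, 0.783), Csf2 (−0.02, 0.967) and Il22 (−0.44, 0.451). Il22 sat at the highest value of the table, 16155.73 FPKM, in both controls, so a higher level in them could not have been seen. The count of 249 was 18, 26, 37 or 11 without NKp46+ control 1, control 2, Setd2-deleted 1 or Setd2-deleted 2, and 91 or 87 without Setd2-deleted 1 or 2 of the NKp46− subset. It was 89 with no filter on low values, 152 without the mean trend in the variance, 150 with a 2-fold threshold, 36 from the 4 NKp46+ libraries alone and 162 with a term for the mix of sexes.

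The NKp46+ and type 1 program had the clearest shift of the lists in NKp46+ cells. Of its 31 genes 13 rose and none fell, and adjusted over the list alone 20 rose and none fell (mean log2 change 0.87). Its adjusted p was 5.09e-18 with the preset correlation, and it was the list that still passed with an estimated correlation (adjusted p = 0.0197 with an estimated correlation). Klrb1c (NK1.1) went from 40.4 ± 3.82 to 119 ± 6.10 FPKM and Tyrobp, a signalling adaptor of activating receptors that myeloid cells also express, from 46.7 ± 7.76 to 155 ± 32.6. Among 23 NK cell receptors 8 rose, Klri2 and Tigit with them, and Klrg1 fell from 17.2 ± 3.09 to 4.22 ± 0.0707 FPKM. Adjusted over the list alone 18 rose and 1 fell (adjusted p = 3.39e-14, and adjusted p = 0.116 with an estimated correlation). Of 16 cytotoxic granule and death ligand genes 3 rose and none fell. These were Gzma, Gzmc (381 ± 26.3 to 1721 ± 667 FPKM) and Nkg7 (332 ± 32.1 to 815 ± 31.6), and 10 rose and 2 fell adjusted over the list alone (adjusted p = 0.00038, and adjusted p = 0.230 with an estimated correlation). The list of markers of NK cells and ILC1s, which shares Gzma and Klrg1, did not pass (3 of 11 rose, with Cd200r1 among them, 1 fell, 5 and 2 adjusted over the list alone, adjusted p = 0.0829).

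The type 17 program did not shift as a whole in NKp46+ cells (adjusted p = 0.476), although 2 of its 30 genes rose, Rorc with them, and Il17a, Il1r1 and Id2 fell (3 rose and 3 fell adjusted over the list alone). Id2, a regulator required for innate lymphoid cells, went from 1508 ± 35.0 to 932 ± 38.3 FPKM, and Il1r1, the IL-1 receptor, from 84.5 ± 0.990 to 42.6 ± 4.33. In the LTi-like signature, genes of lymphoid tissue inducer cells, 2 of 21 rose, Cxcr5 with them, and 3 fell. Nrp1 was one of the falls, at −1.68 on the log2 scale, and 3 rose and 5 fell adjusted over the list alone. Its median was 0.10, its mean −0.14 and its adjusted p 0.911. Secreted cytokines and chemokines moved both ways, 4 of 34 rising (Xcl1, Ifng and Ccl20 among them) and 4 falling (Il17a, Cxcl3 and Cxcl2 among them), with a median of −0.03, a mean of 0.03 and an adjusted p of 0.911. Adjusted over the list alone 7 rose and 6 fell. The cytokine receptors leaned up (adjusted p = 0.0290, and adjusted p = 0.341 with an estimated correlation), with 2 of 38 higher (Il12rb2 among them), 3 lower (Il1r1 and Il17re among them), and 5 up and 3 down adjusted over the list alone. That list no longer passed without NKp46+ Setd2-deleted 2 (adjusted p = 0.123). Cxcr3 (0.73) and Cxcr5 (0.63) rose among 32 trafficking receptors, which did not pass as a list (7 up and 5 down adjusted over the list alone, adjusted p = 0.335).

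In the same NKp46+ comparison a few genes of antigen presentation and of the interferon response changed, alongside markers of macrophages. Of 20 MHC class II genes 5 rose and none fell, Cd74 from 624 ± 2.57 to 1400 ± 118 FPKM, Lgmn from 14.3 ± 1.85 to 35.4 ± 5.45 and H2-Eb1 from 100.2 ± 8.22 to 173 ± 15.2. Adjusted over the list alone 9 rose and 2 fell (adjusted p = 9.32e-05, and adjusted p = 0.124 with an estimated correlation). Of 42 interferon response genes Gbp3 (1.19) and Gbp4 (0.68) rose and Irf7 (−0.68) fell, with 8 up and 1 down adjusted over the list alone (adjusted p = 5.35e-07, and adjusted p = 0.230 with an estimated correlation). Markers of monocytes, macrophages and neutrophils, which also present antigen, rose in 6 of 21 cases and fell in none (13 and none adjusted over the list alone, median log2 change 0.73, adjusted p = 2.24e-10, and adjusted p = 0.230 with an estimated correlation). Lyz2, a lysozyme of these cells, went from 111 ± 5.66 to 214 ± 30.6 FPKM, Apoe from 267 ± 18.4 to 517 ± 29.2 and C1qb from 40.2 ± 1.39 to 82.0 ± 4.19. Epithelial markers shifted up too (2 of 15 rose, 4 adjusted over the list alone, adjusted p = 0.000746, and adjusted p = 0.341 with an estimated correlation), Epcam from 8.76 ± 0.354 to 17.4 ± 1.56 and Krt18 from 3.90 ± 0.665 to 12.9 ± 4.31. T cell markers had a median of 0.33 with no member past the threshold over all genes (5 up and 1 down of 13 adjusted over the list alone, adjusted p = 0.0252, and adjusted p = 0.355 with an estimated correlation), and did not pass without Setd2-deleted 2 (adjusted p = 0.0788). Among 4 B cell genes, too few to test, Ighm rose from 13.1 ± 0.877 to 35.9 ± 4.80 while Blk and Cd79b fell, Cd79b from 51.8 ± 1.43 to 25.3 ± 3.00. Calca (1.56) and Klrg1 (−1.79) changed among 15 ILC2 markers, which did not pass (3 up and 1 down adjusted over the list alone, adjusted p = 0.169), nor did dendritic cell (0.169), stromal (0.108), red blood cell (0.549) or sex-linked genes (0.411).

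A few cell cycle genes rose in NKp46+ cells. In the G1/S list Rpa2 (0.95) and Ccne2 (0.99) rose among 39 genes (4 adjusted over the list alone, mean 0.23, adjusted p = 6.98e-05, and adjusted p = 0.230 with an estimated correlation). In the G2/M list Cdc20 (0.78) rose among 40 (2 adjusted over the list alone, adjusted p = 0.00867, and adjusted p = 0.341 with an estimated correlation), and the list did not pass without NKp46+ control 1 (adjusted p = 0.0901) or Setd2-deleted 2 (0.0554). Cytosolic ribosomal proteins were lower, with a mean of −0.27 over 73 genes, Rps18 (−0.55) and Rps19 (−0.58) past the threshold and 6 lower adjusted over the list alone (adjusted p = 3.02e-12, and adjusted p = 0.402 with an estimated correlation). Rpl29 had not been put on that list. The Notch list was lower, Hes1 falling from 57.1 ± 6.84 to 12.4 ± 0.601 FPKM as its one changed member of 19 (1 up and 5 down adjusted over the list alone, adjusted p = 0.00289, and adjusted p = 0.341 with an estimated correlation). MHC class I genes (mean 0.12, none of 23 changed by either count, adjusted p = 0.0456) and glycolysis genes (mean −0.12, none of 22 changed, 1 lower adjusted over the list alone, adjusted p = 0.0421) passed as lists, both with adjusted p = 0.402 with an estimated correlation. Neither passed without NKp46+ Setd2-deleted 2 (adjusted p = 0.269 and 0.0925) or without NKp46− Setd2-deleted 1 or 2. MHC class I was also lost without NKp46+ control 2 (0.195), and glycolysis without NKp46+ control 1 (0.109) or Setd2-deleted 1 (0.0564). Pmaip1 (1.81) and Plk2 (1.36) rose among 24 p53 targets, Pmaip1 also among 36 apoptosis regulators, Asns (1.43) among 29 genes of amino acid stress and Fos (0.49) among 32 immediate early genes. Parp1 (−0.60) fell among 41 DNA repair genes, Ier2 (−0.46) among immediate early genes and Hspa1a (−0.58) among 18 heat shock genes, while Ccl20 (1.65) rose and Cxcl2 (−0.94) fell among 26 NF-κB targets. None of these lists passed (adjusted p = 0.329, 0.131, 0.131, 0.169, 0.829, 0.811 and 0.543, from p53 targets to immediate early genes and then from DNA repair to NF-κB targets). Adjusted over the list alone they had 2, 4, 2, 2, 0, 0 and 1 genes higher and 0, 0, 0, 3, 1, 2 and 1 lower, in the same order. The lists of lysine 36 methylation enzymes and readers (adjusted p = 0.609), chromatin silencing complexes (0.610) and splicing factors (0.340) had no changed member by either count. That also held for TGF-β (0.108), aryl hydrocarbon and retinoid (0.787), oxidative phosphorylation (0.130), mitochondrially encoded (0.109) and lipid synthesis genes (0.914).

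In NKp46− ILC3s, Setd2-deleted mice again had higher Rorc and lower Il17a and Pcp4 than controls, together with higher Dntt, Cd24a and Il4. Rorc went from 374 ± 1.87 to 1093 ± 10.4 FPKM (SD, n = 2), a log2 change of 1.55 (SE 0.08, adjusted p = 0.00113). Il17a fell from 165 ± 30.8 to 32.9 ± 7.41 FPKM and Ncr1 from 14.4 ± 0.113 to 8.07 ± 0.0849. Dntt, the terminal transferase of lymphocyte progenitors, rose from 4.38 ± 1.85 to 50.3 ± 8.88 FPKM. Cd24a, a surface protein of immature lymphocytes and dendritic cells, rose from 5.04 ± 1.38 to 42.2 ± 9.63.

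The NKp46− comparison gave 340 changed genes, 199 higher and 141 lower. Among the largest rises were Dntt (log2 change 3.29, SE 0.28, adjusted p = 0.00446) and Ccl1, a chemokine, from 1.59 and 0 FPKM to 10.67 and 20.02 (adjusted p = 0.0234). The other 4 of the largest rises were Rnu3b1, Rnu3b2, Rnu3b3 and Rnu3b4, near-identical copies of one small nucleolar RNA on chromosome 11, each of which has 2 gene IDs in the table. One ID of each held the same values, listed at 0 in the 4 control libraries and at 399.11 and 115.98 FPKM in NKp46− Setd2-deleted libraries (Rnu3b1, adjusted p = 0.0381). The other ID of each, at nearly the same coordinates, was at 443.05 and 654.53 FPKM in NKp46− controls and 429.57 and 678.02 in Setd2-deleted libraries (Rnu3b1, adjusted p = 0.999). How reads were divided among these entries is not known, so the rise is uncertain. The largest falls were in Pcp4 (−5.35, SE 0.32, from 479 ± 93.0 to 10.8 ± 2.93 FPKM), Rpl29 (−2.58, SE 0.31, from 64.3 ± 33.5 to 9.22 ± 1.37), Il17a (−2.29, SE 0.20), Dppa2 (a pluripotency-associated protein, −2.29, SE 0.29), Slc6a20a (a transporter of proline, −2.15, SE 0.25) and Bmp2 (a growth factor, −1.96, SE 0.21). Panel genes that did not pass were Ccr6 (0.18, adjusted p = 0.875), Tbx21 (−0.23, 0.540), Gata3 (−0.15, 0.650), Il22 (−0.48, 0.397), Csf2 (−0.56, 0.0981) and Ifng (0.44, 0.165). Il22 was at the top of the table in both controls and at 8302.49 and 16155.73 FPKM in Setd2-deleted libraries. The count of 340 was 143, 37 or 34 without control 1 or Setd2-deleted 1 or 2 of this subset, and 165, 165, 174 or 176 without an NKp46+ library. With no filter it was 153, with a 2-fold threshold 221, and from the 4 NKp46− libraries alone 8.

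Type 17 genes leaned down in NKp46− cells: 3 of 30 fell, Il17a and Id2 with them, and Rorc rose, and 7 fell and 2 rose adjusted over the list alone (median −0.30, adjusted p = 0.0205, and adjusted p = 0.242 with an estimated correlation). That list no longer passed without control 2 (adjusted p = 0.104) or Setd2-deleted 1 (adjusted p = 0.159) of this subset. Id2 went from 1515 ± 80.9 to 871 ± 14.4 FPKM. The LTi-like signature moved both ways, with 3 genes higher, Il17a, Nrp1 (−1.33) and Slc6a20a lower, and 5 up and 5 down of 21 adjusted over the list alone (adjusted p = 0.945). The NKp46+ and type 1 program was higher here as well (8 of 31 rose and Ncr1 fell, 13 and 2 adjusted over the list alone, mean 0.50, adjusted p = 4.35e-06, and adjusted p = 0.0928 with an estimated correlation). Xcl1 went from 16.5 ± 3.01 to 41.0 ± 0.870 FPKM, Tyrobp from 48.1 ± 0.141 to 139 ± 23.9 and Cd160, a receptor of NK and intraepithelial lymphocytes, from 145 ± 17.6 to 298 ± 33.4. Among 23 NK cell receptors 3 rose, Slamf6 (2.64) and Klrb1f (0.65) with them, and Ncr1 (−0.77) fell (6 up and 1 down adjusted over the list alone, adjusted p = 0.00484, and adjusted p = 0.251 with an estimated correlation), and the list did not pass without NKp46− control 2 (adjusted p = 0.0916). Nkg7 (0.90) alone of 16 cytotoxic genes rose (3 up and 1 down adjusted over the list alone), and that list had a median of −0.05, a mean of 0.23 and an adjusted p of 0.587. Itga1 (−1.72) fell and Cd200r1 (0.60) rose among markers of NK cells and ILC1s (4 up and 1 down of 11 adjusted over the list alone, adjusted p = 0.0569).

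Some markers of ILC2s and T cells with low values in controls were higher in NKp46− cells of Setd2-deleted mice. Of 15 ILC2 markers 6 rose and none fell (9 and none adjusted over the list alone, mean 0.85, adjusted p = 1.48e-07, and adjusted p = 0.0928 with an estimated correlation). Il4, a type 2 cytokine, went from 0.350 ± 0.127 to 7.25 ± 2.93 FPKM, Calca, which encodes calcitonin gene-related peptide, from 6.12 ± 0.467 to 25.5 ± 6.83, and Hpgds, a prostaglandin D2 synthase, from 2.31 ± 0.438 to 8.44 ± 1.25. Gata3, which marks ILC2s and is expressed by ILC3s too, did not pass. Of 13 T cell markers 4 rose, Cd3d, Cd247 and Cd28 with them (7 up and 1 down adjusted over the list alone, mean 0.82, adjusted p = 1.97e-06, and adjusted p = 0.150 with an estimated correlation). Cd3d went from 2.28 ± 0.863 to 12.8 ± 4.70 FPKM, Cd247 from 3.37 ± 0.502 to 12.1 ± 0.898 and Cd28 from 0.855 ± 0.0636 to 5.49 ± 1.22. Among 34 secreted cytokines and chemokines 7 rose, Il4, Xcl1 and Ccl1 with them, and 4 fell, Il17a with them (10 up and 5 down adjusted over the list alone, adjusted p = 0.0629). Il17rb (1.41) and Il21r (1.71) rose among 38 cytokine receptors (6 up and 1 down adjusted over the list alone, adjusted p = 0.00650, and adjusted p = 0.190 with an estimated correlation), and without NKp46− control 1 their mean went from 0.25 to 0.17 and the list did not pass (adjusted p = 0.0936). Among 32 trafficking receptors 4 rose, Sell (L-selectin, 2.15), Ccr8 (1.49) and Itgae (1.06) with them, and 3 fell, Itga1 with them (7 up and 7 down adjusted over the list alone, adjusted p = 0.630). Itgae and Itga1 were also the changed members of the TGF-β list (1 up and 1 down of 20 adjusted over the list alone, adjusted p = 0.791).

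Among 21 macrophage markers in this subset 7 rose and none fell (15 and none adjusted over the list alone, median 0.92, adjusted p = 1.43e-12, and adjusted p = 0.150 with an estimated correlation). C1qa went from 37.0 ± 3.10 to 105 ± 22.6 FPKM, C1qb from 51.7 ± 0.785 to 129 ± 22.4 and Apoe from 324 ± 48.3 to 699 ± 71.5. Tff3, a goblet cell peptide, went from 0 and 0.35 FPKM to 10.83 and 4.86, Epcam from 4.64 ± 0.849 to 10.0 ± 0.955 and Cdh1 from 0.215 ± 0.0354 to 1.49 ± 0.163, the 3 changed members of 15 epithelial markers (8 up adjusted over the list alone, adjusted p = 1.57e-05, and adjusted p = 0.150 with an estimated correlation). The mean of the epithelial list was 0.88 with both controls and 0.54 without control 1. Cdh1 passed narrowly (adjusted p = 0.0466, limma) and was lost with a term for the mix of sexes (adjusted p = 0.0739). Cd24a and Bst2 rose among 14 dendritic cell markers (4 up and 1 down adjusted over the list alone, adjusted p = 0.00305, and adjusted p = 0.150 with an estimated correlation). In the MHC class II list H2-Aa (1.01), H2-Eb1 (0.83) and H2-DMb1 (0.92) rose among 20 genes (9 up and 1 down adjusted over the list alone, adjusted p = 3.15e-05, and adjusted p = 0.107 with an estimated correlation). The MHC class I list was also higher (none of 23 changed, 5 up adjusted over the list alone, adjusted p = 0.000149, and adjusted p = 0.150 with an estimated correlation). Interferon response genes rose in 5 of 42 cases, Usp18 (1.10), Isg15 (0.82) and Bst2 (0.80) with them (7 up and 1 down adjusted over the list alone, adjusted p = 0.000152, and adjusted p = 0.190 with an estimated correlation). Ighm (1.68) rose while Blk (−1.40) and Cd79b (−0.88) fell among B cell genes, and Cpa3 rose from 6.25 ± 2.43 to 48.1 ± 8.75 FPKM. Stromal (adjusted p = 0.426), red blood cell (0.0660) and sex-linked lists (0.791) did not pass.

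**Figure D2:**
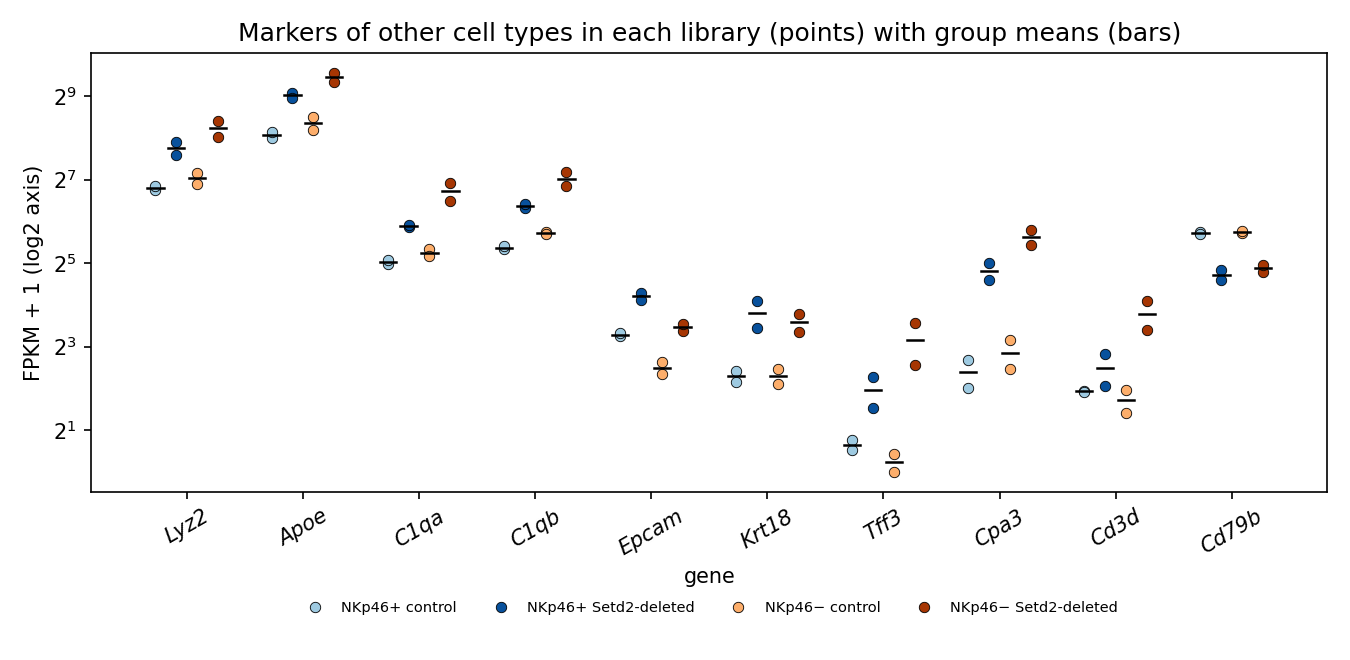
FPKM + 1 on a log2 axis for markers of macrophages (Lyz2, Apoe, C1qa, C1qb), epithelial cells (Epcam, Krt18, Tff3), mast cells (Cpa3), T cells (Cd3d) and B cells (Cd79b), with 1 point per library and a bar at the mean of each group of 2. Apoe was at 253.57 to 358.02 FPKM in the control libraries and at 496.24 to 749.94 in the Setd2-deleted ones. Cd79b was lower in the latter. Some other members of these lists were near 0. Alpi (epithelial cells), Cd19 and Pax5 (B cells) were listed at 0 in every library. Ms4a2 (mast cells) did not exceed 0.04 FPKM and Cd5 (T cells) did not exceed 0.27. Single genes shown here therefore do not establish that these cells were present.

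In NKp46− cells the G2/M list was higher, Top2a (1.09) and Ccnb1 (1.17) passing among 40 (8 adjusted over the list alone, mean 0.32, adjusted p = 4.76e-06), as were G1/S genes (none of 39 changed, 3 up adjusted over the list alone, mean 0.25, adjusted p = 2.17e-05). Both had adjusted p = 0.150 with an estimated correlation. Cytosolic ribosomal proteins were higher here, with a mean of 0.28 over 73 genes and Rpl13a (0.61) past the threshold over all genes but none adjusted over the list alone (adjusted p = 2.32e-12, and adjusted p = 0.505 with an estimated correlation). That mean was 0.13 without NKp46− control 1 and 0.43 without control 2. Bcl2 (0.96) rose and Bcl2a1d (−0.81) fell among apoptosis regulators. Phgdh (1.25) rose among genes of amino acid stress and Fos (0.62) among immediate early genes, while Pfkp (−0.69) fell in glycolysis, Tiparp (−0.53) among aryl hydrocarbon receptor genes and Bmi1 (−1.02) among chromatin silencing genes. None of these lists passed (adjusted p = 0.355, 0.457, 0.470, 0.630, 0.791 and 0.791, in the order named), and adjusted over the list alone they had 1, 3, 1, 1, 0 and 0 genes higher and 1, 0, 0, 3, 2 and 1 lower. The Notch list (adjusted p = 0.146), NF-κB targets (0.924), p53 targets (0.791), lysine 36 methylation (0.924), splicing (0.791), DNA repair (0.924), oxidative phosphorylation (0.791), mitochondrially encoded (0.791), lipid synthesis (0.222) and heat shock lists (0.222) did not pass either. Adjusted over the list alone these held 2 lower Notch genes, 1 higher and 2 lower NF-κB targets (Bcl2a1d over all genes), 4 higher and 3 lower p53 targets and no other changed member.

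**Figure D3:**
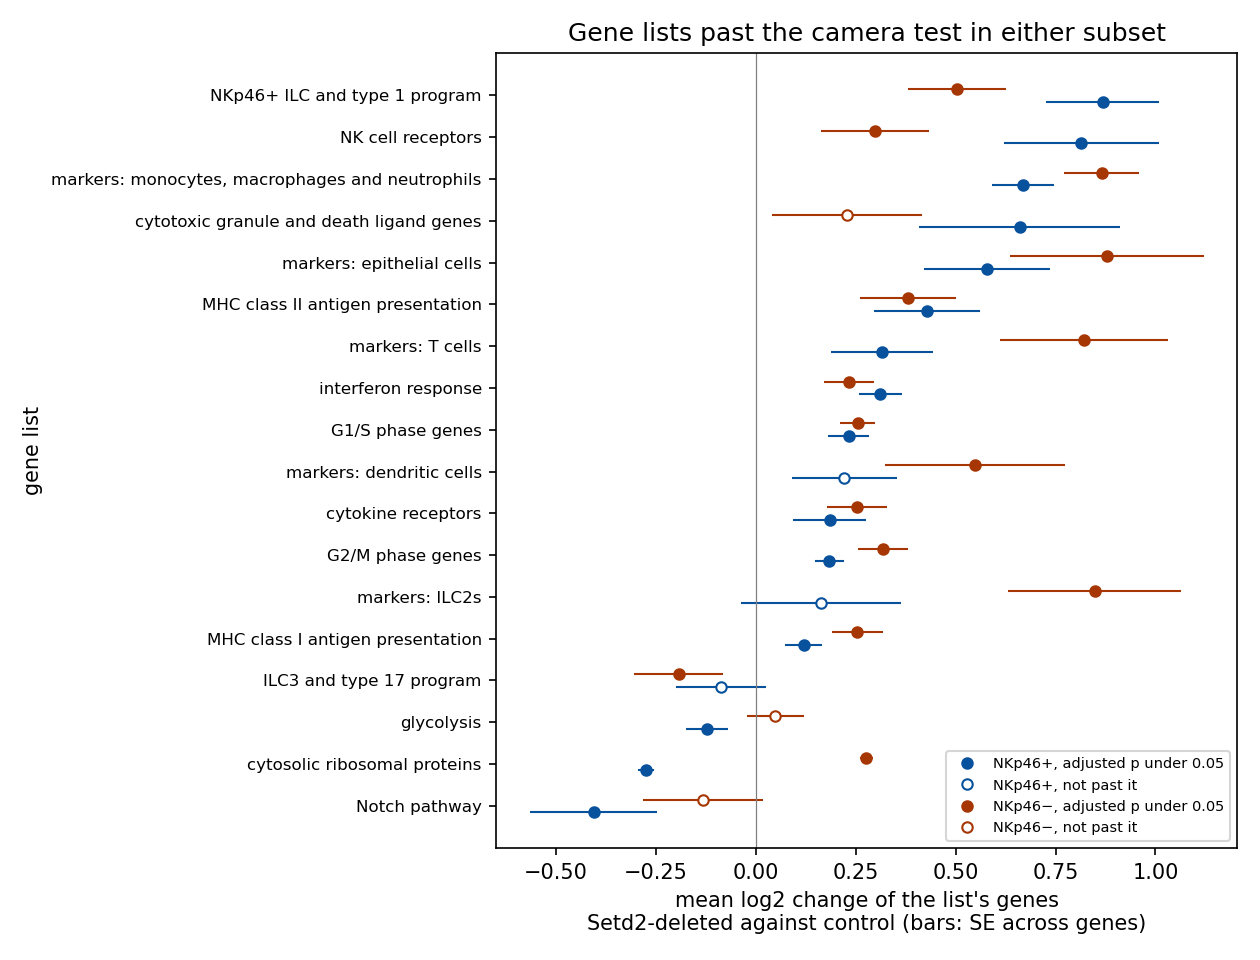
Mean log2 change of the genes of each list past the camera test with the preset correlation in at least 1 subset, with bars for the SE across genes, which are not independent of one another. The NKp46+ and type 1 program had means of 0.87 in NKp46+ and 0.50 in NKp46− cells, and cytosolic ribosomal proteins had means of −0.27 and 0.28 (0.13 without NKp46− control 1).

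The comparisons with control in the subsets share no library, and their changed genes overlapped. Whether the subsets were sorted from the same mice is not stated, and differences between pools of mice would then be shared by the comparisons. In both subsets 49 genes were higher, where independent lists would share 2.42, and 41 were lower, where they would share 0.986. Fisher's exact test gave p = 1.12e-51 and 3.97e-58 across genes, which are not independent replicates. Both comparisons also take the spread of a gene from the same fit of 8 libraries (Rorc, SE 0.08 in both). Genes with a small estimated spread pass more readily in both, so these expected numbers and p-values are not those of unrelated comparisons. Rorc, Xcl1, Tyrobp, Cpa3, Nkg7, H2-Eb1 and Fos were among the genes higher in both. Pcp4, Rpl29, Il17a, Id2, Blk and Nrp1 were among those lower in both. Ncr1 was 1 of 3 genes that changed in opposite directions. Over all genes tested the log2 changes correlated at 0.327 (Pearson) and 0.277 (Spearman), and at 0.188 (Pearson) without NKp46− control 2. With a 2-fold threshold 48 genes were shared in direction in place of 90, and leaving out 1 NKp46+ library or 1 NKp46− Setd2-deleted library left 6 to 23.

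**Figure D4:**
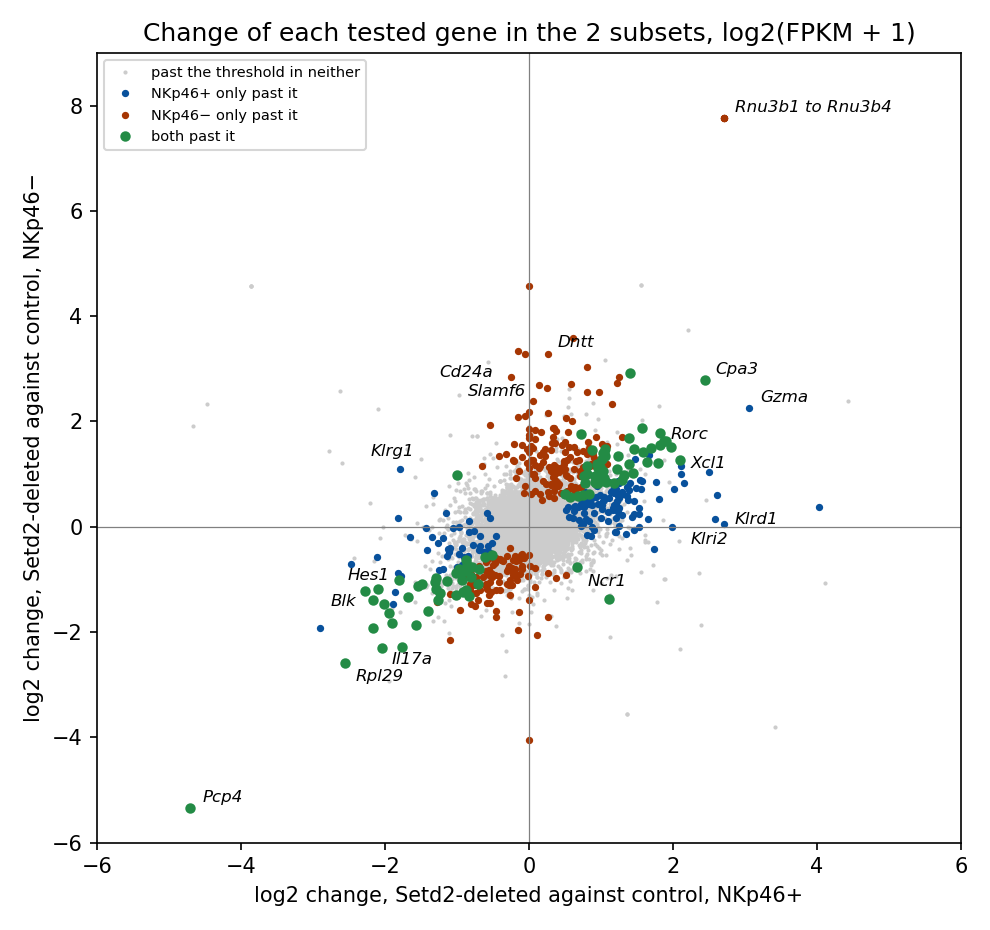
Log2 change of each of 13018 genes in NKp46+ (x axis) and NKp46− ILC3s (y axis) of Setd2-deleted against control mice, on the log2(FPKM + 1) scale, coloured by where it passed the threshold. Pcp4 lay farthest from the origin among genes lower in both (−4.72 and −5.35), and Rorc at 1.82 and 1.55.

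The change with genotype differed between the subsets for 9 genes by the interaction test, 4 with the higher change in NKp46+ cells and 5 with the lower. Ncr1 rose in NKp46+ and fell in NKp46− cells (difference 1.44, SE 0.15, adjusted p = 0.0369). It is the gene of the sorting marker, so its level in each subset also depends on the sort. Klri2 rose in NKp46+ cells from 4.01 ± 0.375 to 29.2 ± 2.35 FPKM and stayed under 1 FPKM in NKp46− cells (difference 2.43, SE 0.25). Cd200r2, a receptor of the CD200 family, rose in NKp46+ cells from 14.5 ± 3.12 to 50.4 ± 1.70 and was at 10.9 ± 0.919 and 7.84 ± 1.05 in NKp46− cells (difference 2.17, SE 0.25). Cd24a rose in NKp46− cells and was at 1.57 ± 0.00707 and 1.16 ± 0.0212 in NKp46+ cells (difference −3.09, SE 0.32). Klrg1, an inhibitory receptor, fell in NKp46+ cells and was at 4.46 ± 0.940 and 10.9 ± 3.10 in NKp46− cells, where its adjusted p was 0.0529 (difference −2.90, SE 0.33). The histone gene Hist1h2ap, which has near-identical copies and is therefore uncertain, had a difference of −1.50 (SE 0.15). Outside the rule for naming, chosen after their values were seen, were Fxyd4 (2.49), Gm4604 (−1.99) and AC140267.1 (−4.57), the last listed at 0 in every library but the NKp46− Setd2-deleted ones. At an unadjusted p under 0.05 there were 1285 genes, and no gene passed in limma with no filter or with a term for the mix of sexes. With any 1 library left out 0 or 1 genes passed, and the 6 genes named by the rule passed in none of these fits (differences of the same sign, adjusted p up to 0.239).

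By the same test the NKp46+ and type 1 program (median difference 0.40, 8 up and 1 down of 31 adjusted over the list alone, adjusted p = 0.000304), NK cell receptors (0.54, 8 up and 2 down of 23, adjusted p = 9.82e-06) and cytotoxic genes (0.33, none of 16, adjusted p = 0.0153) changed more upward in NKp46+ cells. Over all genes Ncr1 passed in the first of these lists, Ncr1, Klri2 and Klrg1 in the NK receptor list, and no gene in the cytotoxic list. Ncr1 is the gene of the sorting marker, and the lists that hold it were not tested without it. Ribosomal proteins (−0.52, 16 down of 73 adjusted over the list alone, none over all genes, adjusted p = 2.00e-31), ILC2 markers (−0.65, 3 down of 15, Klrg1 over all genes, adjusted p = 0.000170) and T cell markers (−0.19, 5 down of 13, none over all genes, adjusted p = 0.0494) changed more downward. None of these 6 lists passed with an estimated correlation (adjusted p = 0.192, 0.367, 0.508, 0.508, 0.192 and 0.574 with an estimated correlation, in that order). Cytotoxic genes were also lost without NKp46+ Setd2-deleted 2 (adjusted p = 0.168) or NKp46− control 2 (0.205). T cell markers were lost without replicate 2 of any of the 4 groups (0.0605 to 0.215). The macrophage and epithelial lists did not differ past the threshold (adjusted p = 0.180 and 0.296), nor did the change of Rorc (difference 0.28, SE 0.12, adjusted p = 0.496), Il17a (0.25, 0.782), Ifng (0.41, 0.534), Csf2 (0.54, 0.481), Tbx21 (0.18, 0.803), Gata3 (0.05, 0.946), Ccr6 (−0.10, 0.964), Il22 (0.04, 0.976) or Setd2 (0.32, 0.726).

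In control mice, NKp46+ ILC3s had more transcripts of natural killer and type 1 genes than NKp46− ILC3s, and fewer of Il17a, Il17f and Ccr6. Ncr1, the gene of the sorting marker, was higher by 4.98 on the log2 scale (SE 0.10, adjusted p = 7.32e-07), which checks the sort and is no finding. Tbx21, the type 1 transcription factor T-bet, was at 48.2 ± 0.559 against 8.80 ± 2.38 FPKM (SD, n = 2) and Ifng at 155 ± 12.9 against 24.4 ± 4.94. Il17a was at 7.33 ± 1.14 against 165 ± 30.8 and Ccr6, a chemokine receptor of LTi-like cells, at 7.41 ± 5.64 against 130 ± 33.4. Rorc was near the threshold (−0.37, SE 0.08, adjusted p = 0.0491), and this call was lost with any 1 library left out (adjusted p up to 0.242) and with a term for the mix of sexes (adjusted p = 0.0736). Gata3 (−0.28, 0.408), Csf2 (0.29, 0.382), Setd2 (0.01, 0.991) and Il22 (at the top value in all 4 libraries) did not differ past the threshold.

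Between the subsets of control mice 530 genes differed, 210 higher in NKp46+ cells and 320 lower. The largest rises after Ncr1 were Slc6a20a (4.46), Klrc1 (an NKG2 receptor, 2.96), Xcl1 (2.87), Fasl (Fas ligand, 2.81) and Nkg7 (2.81), with SE of 0.14 to 0.32. After Il17a (−4.31) and Ccr6 (−4.12) the largest falls were Ptges (prostaglandin E synthase, −3.92), Tspan32 (a tetraspanin, −3.64), Il17f (−3.54) and Pdcd1 (PD-1, −3.50), with SE of 0.18 to 0.40. In the NKp46+ and type 1 program 17 of 31 genes were higher and 2 lower (21 and 3 adjusted over the list alone, adjusted p = 2.19e-16), and this list still passed with an estimated correlation (adjusted p = 0.0237 with an estimated correlation). NK cell receptors (11 higher and 1 lower of 23, 16 and 1 adjusted over the list alone, adjusted p = 1.29e-14) and cytotoxic genes (9 and none of 16, 10 and none adjusted over the list alone, adjusted p = 2.81e-10) both had adjusted p = 0.0751 with an estimated correlation. The program and the NK receptor list count Ncr1 itself and were not tested without it. In the LTi-like signature 13 of 21 genes were lower and Slc6a20a was higher (14 and 1 adjusted over the list alone, adjusted p = 1.29e-14, and adjusted p = 0.0989 with an estimated correlation). Slc6a20a had been put on that list as an LTi-like gene and went the other way. Type 17 genes were lower (6 lower and 1 higher of 30, 7 and 2 adjusted over the list alone, adjusted p = 0.000991, and adjusted p = 0.163 with an estimated correlation). MHC class II genes were lower (5 lower of 20, 7 lower and 1 higher adjusted over the list alone, adjusted p = 0.000142, and adjusted p = 0.0878 with an estimated correlation). G2/M genes were higher (6 higher and 1 lower of 40, 17 and 1 adjusted over the list alone, adjusted p = 1.23e-09, and adjusted p = 0.0878 with an estimated correlation). Heat shock genes were lower (4 of 18, 10 adjusted over the list alone, adjusted p = 2.12e-07, and adjusted p = 0.163 with an estimated correlation). Markers of NK cells and ILC1s were higher (6 of 11 by either count, adjusted p = 0.000142, and adjusted p = 0.0878 with an estimated correlation). Of the other lists of cell markers, stromal and endothelial cells were lower in NKp46+ cells (1 of 15 by either count, mean −0.56, adjusted p = 0.00178, and adjusted p = 0.393 with an estimated correlation). That call was lost without NKp46+ control 1 (adjusted p = 0.148, mean −0.32) or NKp46− control 2 (adjusted p = 0.212, mean −0.24), and the mean was −0.88 without NKp46− control 1. ILC2 markers were lower (3 lower and 1 higher of 15, 5 and 1 adjusted over the list alone, adjusted p = 0.0189, and adjusted p = 0.168 with an estimated correlation). The macrophage list did not pass (adjusted p = 0.258). G1/S genes were higher (2 higher and 1 lower of 39, 5 and 1 adjusted over the list alone, adjusted p = 1.35e-05, and adjusted p = 0.149 with an estimated correlation). Immediate early genes (4 lower and 2 higher of 32, 6 and 2 adjusted over the list alone, adjusted p = 0.000142) and NF-κB targets (3 and 2 of 26, 6 and 2 adjusted over the list alone, adjusted p = 0.000193) were lower, with adjusted p = 0.217 and 0.296 with an estimated correlation. Without NKp46− control 2 their means went from −0.24 to −0.13 and from −0.27 to −0.16. Splicing, MHC class I, oxidative phosphorylation and lipid synthesis lists passed (adjusted p = 0.00399, 0.0333, 0.0168 and 0.0486) with no changed member by either count, and none passed with an estimated correlation (adjusted p = 0.287, 0.296, 0.393 and 0.450 with an estimated correlation). The last 3 were also lost without NKp46+ control 1 (adjusted p = 0.141, 0.148 and 0.579). MHC class I was also lost without NKp46− control 1. Oxidative phosphorylation was lost without NKp46− control 2 (adjusted p = 0.394). Lipid synthesis was lost without any 1 NKp46− library (adjusted p up to 0.106). The oxidative phosphorylation mean was 0.10. It was 0.16 without NKp46− control 1 and 0.04 without control 2. The lipid synthesis mean was 0.19. It was 0.08 without NKp46+ control 1 and 0.29 without control 2. The count of 530 was 181, 183, 352 or 296 without NKp46+ control 1 or 2, NKp46+ Setd2-deleted 1 or NKp46− control 2, 283 with no filter, 300 with a 2-fold threshold and 122 from the 4 control libraries alone.

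In Setd2-deleted mice 1659 genes differed between the subsets, 785 higher in NKp46+ cells and 874 lower. Of these, 405 differed in the same direction in control mice and 3 in the opposite one. Ncr1, the gene of the sorting marker (6.42, SE 0.10), Ifng (3.04), Tbx21 (2.53) and Csf2 (0.83, adjusted p = 0.0117) were higher in the NKp46+ subset. Il17a (−4.06) and Ccr6 (−4.22) were lower in it. Rorc was at 1023 ± 12.0 against 1093 ± 10.4 FPKM (−0.10, adjusted p = 0.470), and Setd2 (0.32, 0.331), Gata3 (−0.23, 0.343) and Il22 (0.04, 0.932) did not pass either. Of 73 cytosolic ribosomal proteins 46 were lower and none higher in NKp46+ cells (62 and none adjusted over the list alone, mean −0.55, adjusted p = 3.29e-22, and adjusted p = 0.317 with an estimated correlation). NK cell receptors were higher in 17 of 23 cases and lower in 2 (20 and 2 adjusted over the list alone, adjusted p = 8.41e-14, and adjusted p = 0.0807 with an estimated correlation). ILC2 markers were lower in 8 of 15 cases and higher in none (11 and none adjusted over the list alone, adjusted p = 1.05e-07, and adjusted p = 0.0758 with an estimated correlation). The NKp46+ and type 1 program again passed with an estimated correlation (20 higher and 2 lower of 31, 22 and 3 adjusted over the list alone, adjusted p = 0.0336 with an estimated correlation). This program and the NK receptor list count Ncr1 and were not tested without it. Markers of macrophages were lower in 2 of 21 cases and higher in none by either count (mean −0.26, adjusted p = 0.0284, and adjusted p = 0.556 with an estimated correlation). That call was lost without NKp46+ Setd2-deleted 2 (adjusted p = 0.0734) or NKp46− Setd2-deleted 1 (adjusted p = 0.220, mean −0.10), and the mean was −0.42 without NKp46− Setd2-deleted 2. Dendritic cell markers were lower in 4 of 14 and higher in 1 by either count (adjusted p = 0.0172, and adjusted p = 0.214 with an estimated correlation). Markers of NK cells and ILC1s were higher in 5 of 11 and lower in 1 (6 and 2 adjusted over the list alone, adjusted p = 0.0183, and adjusted p = 0.214 with an estimated correlation), and were lost without NKp46+ Setd2-deleted 2 (adjusted p = 0.0547). LTi-like genes were lower in 16 of 21 cases and higher in 1 by either count (adjusted p = 1.02e-10, and adjusted p = 0.170 with an estimated correlation). The count of 1659 was 481, 755, 505 or 563 without NKp46+ Setd2-deleted 1 or 2 or NKp46− Setd2-deleted 1 or 2, 978 with no filter and 729 with a 2-fold threshold.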

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

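The interaction test was planned, and all tests of explanations for the patterns below were chosen after the result was seen. Results are given here because the change with genotype differed between NKp46+ and NKp46− ILC3s by the interaction test (limma for genes, camera for lists). The change was higher in NKp46+ cells by 2.49 on the log2 scale for Fxyd4 (chosen after its values were seen), 2.43 for Klri2, 2.17 for Cd200r2 and 1.44 for Ncr1. It was lower for Hist1h2ap (−1.50), Gm4604 (−1.99, chosen after its values were seen), Klrg1 (−2.90), Cd24a (−3.09) and AC140267.1 (−4.57, chosen after its values were seen). Their adjusted p lay between 0.0369 and 0.0498. AC140267.1 was listed at 0 in 6 libraries and at 33.85 and 15.09 FPKM in the NKp46− Setd2-deleted ones.

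By camera with the preset correlation, median differences were 0.3995 for the NKp46+ and type 1 program, 0.54 for NK cell receptors, 0.327 for cytotoxic granule and death ligand genes, −0.521 for cytosolic ribosomal proteins, −0.189 for T cell markers and −0.651 for ILC2 markers. None of these lists passed with an estimated correlation, and with any 1 library left out 0 or 1 genes passed.

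Rorc was higher in both subsets of Setd2-deleted mice, by 735 FPKM on average in NKp46+ and 719 in NKp46− cells. Transcripts of the Rorc-cre construct that carry Rorc sequence would add a similar amount to each subset, and the log2 changes differed by 0.279 between the subsets with an SE of 0.12. More active RORγt was read from 6 textbook targets, whose median log2 change was −0.180 in NKp46+ and −0.41 in NKp46− cells. Il17a was lower in both subsets while Ccl20 was higher in NKp46+ cells, so the targets went both ways. These explanations and an effect of Setd2 loss cannot be told apart, because no group carries Rorc-cre with unfloxed Setd2 and the table holds no values per exon.

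Some markers of macrophages (6 and 7 of 21) and of epithelial cells (2 and 3 of 15) were higher in Setd2-deleted libraries of NKp46+ and NKp46− cells, and these list calls were lost with an estimated correlation (adjusted p = 0.230 and 0.150 for macrophages, 0.341 and 0.150 for epithelial cells). The NKp46− epithelial mean was 0.88, and 0.54 without control 1. Of the 21 macrophage markers, the 19 with a mean of at least 1 FPKM had a positive change in 94.7% of cases in each subset (median 0.75 and 1.01), which restates the pattern and does not test its source. More macrophages or their free RNA in the pools and higher expression within ILC3s cannot be told apart, since no markers outside the pattern were set aside for a test. A lower share of ILC3s would raise every other cell type alike. Stromal and endothelial markers had a median of 0.292 in NKp46+ cells (quartiles 0.16 to 0.35), against quartiles of 0.62 to 0.95 for macrophage markers. The mean log2 level of the stromal list was 3.03 and 3.50 in NKp46+ controls and 3.50 and 4.14 in NKp46− controls. It was 3.99 and 3.98 in NKp46− Setd2-deleted libraries. With such a spread between control replicates, these values cannot decide on a lower share of ILC3s. A larger macrophage population in the gut of Setd2-deleted mice, as a biological source of such RNA, was not tested.

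Among 41 genes lower in both subsets, 4 pairs lay within 200 kb of one another. Of 10000 random draws of as many genes, 0.18% gave as many pairs (p = 0.0019, permutation test). The pairs were seen before this test was chosen, and the draws do not count pairs clear of overlap alone. Chance placement is therefore left open for the 1 clear pair. Reads shared between overlapping annotations stay open for 3 of these pairs, Igsf5 and Pcp4, Zfp414 and Pram1, and Furin and Gm44851, which overlap or are bridged by an annotated transcript. With 1 clear pair of 4, Blk and Fam167a, 19357 bp apart on chromosome 14, chance, shared reads and shared regulation cannot be told apart. Among 49 genes higher in both subsets there were also 4 such pairs (0.53% of draws, p = 0.0054, permutation test), all clear of overlap: H2-DMb1 and H2-Aa, H2-Aa and H2-Eb1, C1qb and C1qa, and Tceal8 and Bex3, so neighbours were not confined to falls (gene pairs chosen after their values were seen).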

How the results depend on the processing

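Alternatives were planned, except the term for the mix of sexes and the protein-coding restriction, which were chosen after the data were seen. Each comparison is given in the order NKp46+ (249 genes changed with genotype), NKp46− (340), their difference (9), and the subsets of control (530) and of Setd2-deleted mice (1659). Pseudocounts of 0.1 and 0.5, a mean filter, a robust fit, other scalings and protein-coding genes alone kept every count within 1.5 times. The scalings move almost nothing, because the columns share one distribution. With no filter the counts were 89, 153, 0, 283 and 978. Of the 148 calls of genes named by the rule, 71 were lost with no filter and 49 without the mean trend in the variance. Fits of only the 4 libraries compared lost 103 of the 142 calls they covered. A 2-fold threshold gave 150, 221, 300 and 729 without the difference, whose 9 genes all passed, and 48 shared genes in place of 90. Without the mean trend NKp46+ cells had 152 and the difference 2, and a filter of 5 FPKM left 5 for the difference. A term for the mix of sexes gave 162 and 0 for these, and 37 of the 148 calls of named genes were lost with it. In NKp46+ cells these were Cxcr3, Cxcr5, H2-Eb1, Gbp3, Irf7, Cxcl2, Parp1, Ccne2, Cdc20, Rps18, Rps19, Ier2, Fos, Krt18, Epcam and Lyz2. In NKp46− cells they were Rnu3b1 to Rnu3b4, Il17rb, H2-DMb1, Isg15, Itgae, Tiparp, Bmi1, Ccnb1, Rpl13a, Cdh1 and Cd200r1. The rest were the interaction genes named by the rule and Rorc between the subsets of control mice. Fits of only the 4 libraries compared gave 36 (NKp46+), 8 (NKp46−), 122 (subsets of control mice) and 1606 (subsets of Setd2-deleted mice), with 2 residual degrees of freedom.

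Leaving out 1 library at a time leaves a group with 1 library that is assumed to vary like the others. The counts then ranged from 11 (without NKp46+ Setd2-deleted 2) to 345, from 34 (without NKp46− Setd2-deleted 2) to 293, from 0 to 1, from 181 (without NKp46+ control 1) to 435 and from 481 (without NKp46+ Setd2-deleted 1) to 2303 (without NKp46− control 1). Shared genes ranged from 6 to 72. Of the 148 calls of genes named by the rule, 34 passed with any library left out and 15 with none, and none of these 148 changed direction under any setting. Those lost whichever library was left out were, in NKp46− cells, H2-DMb1, Itgae, Tiparp, Bmi1, Ccnb1, Rpl13a, Cdh1 and Cd200r1. The others were the interaction genes named by the rule and Rorc between the subsets of control mice. Fewer libraries lower the power of each test, which cannot account for the gene counts that rose without an NKp46− control. A group with 1 library adds nothing to the shared estimate of the spread. The NKp46− controls were the group with the widest replicates (median absolute log2 difference 0.251, against 0.164 to 0.190 in the other groups). Whether this accounts for the rises, or another cause does, was not tested.

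Lists past the threshold fell with an estimated correlation from 15 to 1, from 15 to 0, from 6 to 0, from 18 to 1 and from 17 to 1, in the same order. Fry gave 9 for NKp46+ cells and 3 for the difference. For the difference, list calls ranged from 4 to 11 (without NKp46− control 1) with 1 library left out. The cytosolic ribosomal protein list in the subsets of control mice turned with NKp46− controls: its adjusted p was 0.929 with all libraries, 6.74e-05 without control 1, 0.000102 in the opposite direction without control 2, and 0.114 to 0.927 with any other library left out. The cause was not tested.

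The labels give groups the same replicate numbers without saying that they mark a shared animal or day. With the number as a replicate block the counts were 160, 224, 0, 447 and 1483. Correlations of replicate differences between groups lay between −0.169 and 0.0937, which gives no sign of pairing across genes. The sex score was lower in replicate 1 than in replicate 2 in all 4 groups. It ran in the same order in both subsets, from control 1 over Setd2-deleted 1 and Setd2-deleted 2 to control 2. The subsets of one genotype and number could therefore have come from one pool of mice, and pairing stays open. The block joins numbers across genotypes and does not stand for such pools. No test of the subsets or of the difference modelled them.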

Other observations

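No test in this part was chosen before the data were seen, apart from the subset comparisons and their lists. In Setd2-deleted mice the subsets differed in further gene groups. Secreted cytokines and chemokines were lower in NKp46+ than in NKp46− cells for 16 of 34 genes and higher for 4 (16 and 6 adjusted over the list alone, adjusted p = 0.00463, and adjusted p = 0.144 with an estimated correlation). T cell markers were lower for 7 of 13 and higher for 2 by either count (adjusted p = 0.00722, and adjusted p = 0.287 with an estimated correlation). MHC class II (4 of 20 lower by either count), NF-κB (8 lower and 2 higher of 26, 15 and 3 adjusted over the list alone), immediate early (9 and 1 of 32, 13 and 2 adjusted over the list alone) and heat shock lists (7 and 0 of 18, 8 and 0 adjusted over the list alone) were lower (adjusted p = 0.00198, 0.000896, 0.00149 and 0.00105, and adjusted p = 0.144, 0.387, 0.317 and 0.317 with an estimated correlation). The NF-κB mean was −0.31, and −0.19 without NKp46+ Setd2-deleted 1. G1/S (6 higher and 1 lower of 39, 9 and 2 adjusted over the list alone) and G2/M lists (7 and 2 of 40, 12 and 2 adjusted over the list alone) were higher (adjusted p = 0.00198 and 0.000415, and adjusted p = 0.267 and 0.214 with an estimated correlation). Cytotoxic genes were higher for 10 of 16 and lower for 1 (11 and 1 adjusted over the list alone, adjusted p = 4.55e-08, and adjusted p = 0.0807 with an estimated correlation).

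The SD of the log2 differences over all genes was 0.615 in Setd2-deleted and 0.482 in control mice. Past the threshold in Setd2-deleted mice alone were 1251 genes and in control mice alone 122, which is no test of a difference: the interaction test called 9 genes, and 1659 calls became 481 to 755 without 1 Setd2-deleted library. The median absolute log2 difference between replicates was 0.251 in NKp46− controls and 0.164 to 0.190 in the other groups.

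Rpl29, lower in both subsets, has pseudogene copies named after it in the table, none of them above 1.09 FPKM in any library. Copies listed under other symbols were not looked for, so reads shared with such copies stay open. A sex score (log2 expression of Xist minus the mean of 4 Y-linked genes) ran from −3.57 to 1.05 over the libraries and differed within groups, with −3.57 and 0.53 in the NKp46+ controls and −2.93 and 1.05 in the NKp46− controls, and −2.52 and −1.22 (NKp46+) and −1.51 and −0.22 (NKp46−) in the Setd2-deleted groups. The pools thus held different mixes of males and females.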
